A study of Mus musculus with 4 samples.

How the data were processed

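The series holds 4 arrays of mouse embryonic fibroblasts, 1 for each combination of 2 genotypes (wild type and NFAT5 knockout) and 2 media (isotonic and hypertonic). Per the labels' protocols, cells that had not been synchronised were kept for 20 hours in their medium, and NaCl was added to reach 450 mosmol/kg in the hypertonic medium; the isotonic osmolality is not given in the sources used here. Per the series' design text, quadruplicate samples of each condition were pooled before hybridisation, so each array averages 4 samples and the spread among them is not seen. Total RNA was amplified from a poly(T) primer and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, per the labels' protocols.

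The deposited table holds 1 value per probe set and array, taken here as log2 signal made by the authors. The scale was read from the values, which run from 1.57 to 13.94 with a median near 4.9 on each array. The submitters' processing notes name MAS5, with no version; the background correction and the normalization between arrays are not given in the sources used here. The array medians were nearly equal but the distributions were not identical. Values were used as deposited, and scanner files and detection calls were not used here.

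Probe sets were named from the platform annotation. Of 35557 probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 had none, and the last 2 kinds were left out of all gene results. Of the one-gene probe sets, 21698 matched a RefSeq gene with the same symbol by Entrez identifier. They covered 19938 genes, 999 of them with at least 2 probe sets, for which the probe set with the highest mean over the 4 arrays was used. For list members 10 older symbols were updated. No genome build is named for the table, so no coordinates are given.

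A gene was measured in a comparison when its signal was above the dim limit, the median of the one-gene probe sets of an array, on at least 1 of the 2 arrays compared, or of the 4 arrays for the difference of responses. The dim limits were 5.43 and 5.44 for wild-type isotonic and hypertonic, and 5.38 and 5.41 for knockout-labelled isotonic and hypertonic arrays. Signals below them mix background with expression, so a fold taken from such a signal is poorly determined. The comparisons made were the hypertonic response of each genotype, the genotype difference in each medium, and the difference of the responses. Genes were counted at a fixed limit of 2-fold, 1 on the log2 scale. With 1 array per group, no p-value, standard error or replicate check could be had for these differences. A fit of genotype plus medium, which leaves 1 degree of freedom and takes the difference of responses as error, was not used here. Values with the knockout-labelled arrays in the reverse order were added after the results were seen.

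Genes were named by a rule set before the data were examined: Nfat5, then the 12 highest and 12 lowest differences among counted genes of each comparison, leaving out provisional symbols, and from each fixed list the members past 2-fold and the 4 with the largest absolute difference. The text uses a subset of these, and a gene chosen after its values were seen is said to be so. In addition, 29 pathway lists and 9 cell type lists were fixed before the data were examined. For each list the median difference of its members above the dim limit on any array was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these arrays and is not a test.

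The counting and list steps were tested on simulated data for each of the 4 comparisons between arrays, with 50 genes at each of 1.5-fold, 2-fold, 3-fold and 4-fold. The noise was normal and set from the robust SD of the real differences, true ones included, which is based on their median absolute deviation. That SD is little moved by the largest differences, so the noise had no long tails. Of 100 random lists without a shift, 3, 8, 4 and 7 fell outside the middle 95% in the wild-type response, the knockout-labelled response, the isotonic genotype difference and the hypertonic genotype difference. Of 100 lists shifted by 0.3, 100, 90, 99 and 67 were found. Noise was drawn for each gene separately, so the small share of unshifted lists outside was built in. Lists whose members move together were not simulated. In the real data 75 list medians, taken over all comparisons, fell outside, so an extreme percentile was not rare. The spread between probe sets of the same gene was used to describe measurement error within an array.

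Alternatives set before the data were examined were quantile normalization, cyclic loess normalization, differences centred on their median, no limit on dim genes, a dim limit at the 75th percentile, the mean of a gene's probe sets, and a limit of 1.5-fold. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for the quantile and loess normalizations.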

Results

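Gene expression was measured in mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, either wild-type or labelled as NFAT5 knockout. NFAT5, also called TonEBP, is a transcription factor that switches on genes for taking up and making organic osmolytes when the medium around a cell becomes hypertonic. Wild-type cells and cells labelled as NFAT5 knockout were kept for 20 hours in isotonic medium or in medium raised to 450 mosmol/kg with NaCl. Each of the 4 combinations was read on 1 Affymetrix Mouse Gene 1.0 ST array, hybridised with a pool of 4 samples. With 1 array per group there was no spread between replicates to set a difference against, so no statistical test was made, and every value below describes these 4 pools. All differences are on the log2 scale, and a gene was counted when its signal differed at least 2-fold between the arrays compared.

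The 4 arrays had similar ranges. Median signal over all 35557 probes was 4.91 for wild-type isotonic, 4.90 for wild-type hypertonic, 4.87 for knockout-labelled isotonic and 4.89 for knockout-labelled hypertonic cells. Correlations between arrays across probes lay between 0.979 and 0.989, and the knockout-labelled hypertonic array had the lowest, 0.980 and 0.979 against the wild-type arrays. The median differences of the housekeeping list, 13 measured genes, lay between -0.03 and 0.04 in the 4 comparisons between arrays.

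The Nfat5 probe set did not read lower in the knockout-labelled cells. Its signal was 7.74 in wild-type isotonic, 8.19 in wild-type hypertonic, 8.03 in knockout-labelled isotonic and 8.24 in knockout-labelled hypertonic cells. The labels do not give the deleted part of the gene, and a probe set lying mostly outside a deletion does not check the label, so the cells are called knockout-labelled throughout.

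The first comparison asked which genes respond to hypertonic medium in wild-type cells. Some osmolyte transporter genes and other tonicity genes were higher in hypertonic medium. Slc6a12, the betaine transporter, was higher by a log2 difference of 2.32, Slc5a3, the myo-inositol transporter, was higher by 1.80, and Aqp1, a water channel, by 1.65. Ranbp3l had the largest positive difference of all counted genes with an established symbol, 3.45, from a signal of 3.31 in isotonic medium. That signal and the 4.06 of Slc6a12 lay below the dim limit, the median of the array's one-gene probe sets, so the sizes of these differences are poorly determined. The small heat shock protein gene Cryab was higher by 2.21 and the sodium pump subunit gene Atp1b1 by 1.62. In all, 102 genes were at least 2-fold higher and 42 were at least 2-fold lower among 10134 measured. The smaller of the 2 signals lay below the dim limit for 28 of the higher and 14 of the lower genes.

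Of the 24 measured members of the osmolyte and tonicity list, 19 were above 0 and 4 passed 2-fold, all upward. Those 4 were Slc6a12, Slc5a3, Aqp1 and Ranbp3l, all named above. The list's median was 0.33, at percentile 100 among 10000 random lists of the same size and similar expression, as a description of these arrays. The potassium channel gene Kcnj2 (2.21), the neuropeptide Y receptor gene Npy1r (2.56), the cysteine dioxygenase gene Cdo1 (2.37), and the insulin-like growth factor binding protein genes Igfbp5 (2.25) and Igfbp7 (2.20) were also among the genes higher in hypertonic medium. So were Prss35 (3.13), Itm2a (2.57), Ifi27l2a (2.54), Slco4a1 (2.26) and Ddit4l (2.25). Of these genes, Kcnj2, Npy1r, Prss35, Ifi27l2a, Slco4a1 and Ddit4l read below the dim limit in isotonic medium, so their sizes are poorly determined too.

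Interferon-response genes were higher as a group in the wild-type hypertonic cells. The list's 30 measured members had a median of 0.73 (percentile 100), and 9 passed 2-fold, all upward. Examples are Irf7, a transcription factor of the interferon response (1.54), Ifit3 (1.52), Gbp3 (1.48) and the RNA helicase gene Dhx58 (1.27). The 29 measured genes of TGF-beta, BMP and WNT signalling had a median of 0.24 (percentile 99.99), or 0.14 with dim genes included, with Id3 (1.52), Id2 (1.39) and Tgfbi past 2-fold. Collagens and matrix genes had a small positive median of 0.14 over 37 genes (percentile 99.97). Tnc, encoding tenascin C, was higher by 1.38 and Fmod, encoding fibromodulin, by 1.22, while Has2, a hyaluronan synthase gene, was lower (-1.20).

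Ribosome biogenesis and MYC targets had a median of -0.66 over 27 genes (percentile 0.0), with Rrp12 (-1.26) and the spermidine synthase gene Srm past 2-fold, followed by Gnl3 (-0.98) and Utp20 (-0.83). The amino acid stress list had a median of -0.40 over 33 genes (percentile 0.0), with the cystine transporter gene Slc7a11 (-1.46), the cationic amino acid transporter gene Slc7a1 (-1.18) and Atf3 (-1.13) past 2-fold. The cyclin genes Ccnd2 (-1.41) and Ccnd1 (-1.25) and the hexokinase gene Hk2 (-1.26) were also lower. Gjb2, a gap junction gene, had the lowest difference, -3.50, to a signal of 5.10 below the dim limit. Genes of G1/S and DNA replication (median -0.03) and of G2/M and mitosis (0.00) lay within the range of the random lists, with Ccnd1 the 1 gene of both lists past 2-fold.

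Measurement error was gauged from the 605 genes read by 2 probes, whose differences varied between probes with an SD of 0.15 per probe. Data were also simulated with normal noise set from the robust SD of the real differences, true ones included. There, 100% of 3-fold changes, 56.0% of 2-fold changes and 0.01% of unchanged genes passed 2-fold in this comparison. That noise had no long tails, so the share of unchanged genes that passed is not an upper limit, here or in the comparisons below.

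**Figure D1:**
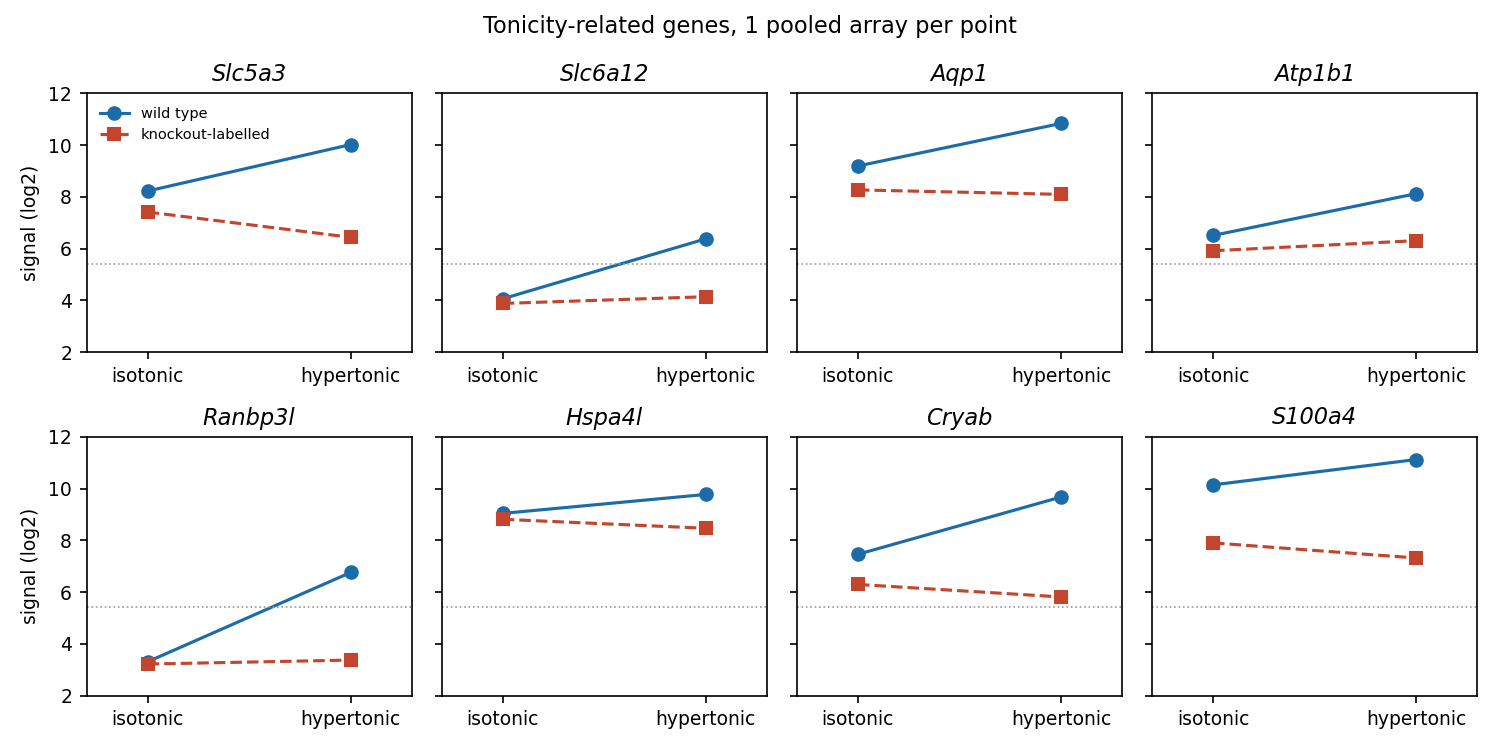
Log2 signal of 8 tonicity-related genes on the isotonic and hypertonic arrays of wild-type cells (circles, solid line) and knockout-labelled cells (squares, dashed line), 1 pooled array per point, with the mean dim limit of the 4 arrays as a dotted line. Slc5a3 read 8.23 and 10.03 in wild-type cells but 7.42 and 6.44 in knockout-labelled cells, and Slc6a12 read 4.06 and 6.38 against 3.88 and 4.14. The 8 genes were picked for display and include the 4 osmolyte and tonicity list members past 2-fold in wild-type cells.

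The second comparison made the same contrast in knockout-labelled cells. None of the 102 genes that were at least 2-fold higher in wild-type cells was 2-fold higher here. Independent lists would give 0.4, so that absence says little. In the other direction, 20 of the 102 were at least 2-fold lower. Ranbp3l differed by 0.15, Slc6a12 by 0.26, Aqp1 by -0.17 and Cryab by -0.48, and Slc5a3 was lower in hypertonic medium (-0.98). Ranbp3l and Slc6a12 read below the dim limit on both knockout-labelled arrays, so their differences here mostly describe background. The lowest differences included matrix and secreted proteins: the small leucine-rich proteins Ogn (-3.61) and Aspn (-3.32), tenascin C (Tnc, -2.26), pentraxin 3 (Ptx3, -2.18) and the aggrecan-cleaving protease Adamts5 (-1.89). Among higher genes were the collagenase gene Mmp13 (2.29), the stromelysin gene Mmp10 (1.66), the arginase gene Arg1 (1.87) and the prolactin-family gene Prl2c5 (3.29), all of which read below the dim limit on the isotonic array, as Ogn, Aspn and Tnc did on the hypertonic array. The order of the knockout-labelled arrays rests on their labels alone. In the reverse order every difference and list median of this comparison changes sign: 20 of the 102 genes are then higher and none is lower, and Slc5a3 differs by 0.98.

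In this comparison 39 genes were at least 2-fold higher and 317 at least 2-fold lower among 10277 measured, with the smaller signal below the dim limit for 20 and 100 of them. That split depended in part on scaling: quantile normalization moved the median difference of all genes from -0.09 to 0.01 and gave 63 higher and 215 lower, and centring on the median gave 66 and 233. Cyclic loess moved that median to -0.02 and gave 39 higher and 269 lower. The share of higher genes was 10.96% as deposited, 22.66% after quantile normalization, 22.07% after centring and 12.66% after cyclic loess.

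Lists that were lower in the knockout-labelled hypertonic cells included interferon response (median -0.63, 8 of 30 genes at least 2-fold lower, none higher), collagens and matrix (-0.43, 6 of 37 lower), and glycolysis and hypoxia (-0.52, 7 of 25 lower), each at percentile 0.0. The interferon examples are Ifit3 (-1.58), Iigp1 (-1.43), Tap1 (-1.35) and Dhx58 (-1.19). Col1a2, a chain of type I collagen, was lower by a log2 difference of -1.20, and Lama4, Lox and Postn had differences of -1.63, -1.59 and -1.41. In the glycolysis and hypoxia list, Pdk1 (-2.07), Bnip3 (-1.40), the lactate transporter gene Slc16a3 (-1.20) and P4ha1 (-1.12) were lowest. The endoplasmic reticulum stress list had a median of -0.35 over 22 genes (percentile 0.04) and the proteasome list -0.25 over 31 genes (percentile 0.10), or -0.16 after centring, with no member past 2-fold in either.

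The amino acid stress list was lower here too, with a median of -0.38 (percentile 0.0), next to -0.40 in wild-type cells. Slc7a11 was at least 2-fold lower in both genotypes, -1.46 and -1.50, and Cth, encoding an enzyme of cysteine synthesis, differed by -0.98 in wild-type cells and passed 2-fold in knockout-labelled cells. Immediate early genes (median 0.31 over 25 genes), p53 targets (0.22 over 26), lysosome and autophagy genes (0.17 over 27) and ion and water transport genes (0.18 over 21) had positive medians at percentiles of 99.90 or above. Under other settings these medians reached 0.37 for p53 targets, 0.27 for lysosome and autophagy genes and 0.28 for ion and water transport genes. Dusp4 (1.03) was the 1 gene of these lists past 2-fold. The osmolyte and tonicity list had a median of 0.06 (percentile 96.34), with Slc6a9 (-1.02) past 2-fold.

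Probe differences had an SD of 0.19 per probe over 617 genes. In simulated data for this comparison 90% of 3-fold and 46.0% of 2-fold changes passed 2-fold, with 0.85% of unchanged genes.

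The responses of the genotypes were then set against each other. Across 10542 genes they were uncorrelated, with Pearson's r of -0.02 and Spearman's rho of 0.01; genes are not independent replicates, and the responses share no array. Of the 102 genes higher in wild-type cells, 71 were below 0 in knockout-labelled cells, with a median of -0.29. Both values take all 102 genes, measured in knockout-labelled cells or not. Some, such as Ranbp3l, Prss35 and Igfbp5, read below the dim limit on both knockout-labelled arrays, so their signs mostly describe background. The 20 that were 2-fold lower compare with 3.28 for independent lists. They included matrix genes (Aspn, Ogn, Omd, Tnc), interferon-induced genes (Ifit3, Irf7, Gbp3, Dhx58, Oasl2) and the glutamate transporter gene Slc1a3. No gene was at least 2-fold lower in wild-type and higher in knockout-labelled cells, against 0.17 for independent lists. The 2 genes lower in both, against 1.35 for independent lists, were Slc7a11 and Dhrs9 (-1.08 and -1.09), the latter named after its values were seen.

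The knockout-labelled response minus the wild-type response was at least 2-fold negative for 583 genes and at least 2-fold positive for 149. With the knockout-labelled arrays in the reverse order, 205 are negative and 524 positive. Aspn (-5.40), Ogn (-5.00), Tnc (-3.65), Prss35 (-3.62), Ranbp3l (-3.30) and Ifit3 (-3.10) were among the most negative. In the reverse order Aspn (1.24), Ogn (2.22) and Tnc (0.88) turn positive, Ifit3 (0.07) lies near 0, and Ranbp3l (-3.61) and Prss35 (-2.64) stay negative. Prl2c5 had the largest positive difference. Other positive differences included Gjb2 (2.91), Mmp13 (2.15), the growth factor gene Pdgfb (1.90), the transcription factor gene Etv4 (1.91), Ccn2, encoding connective tissue growth factor (2.12), and Jun (1.71). The Gjb2 value arose from the wild-type isotonic array, where it read 8.60 against 5.10, 5.17 and 4.58 on the others.

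By list, the interferon response had a median difference of -1.27 with 20 of 30 genes past 2-fold, all negative, and collagens and matrix -0.62 with 12 negative and 1 positive. That positive gene was Lamb1, a laminin chain (1.71). In the reverse order of the knockout-labelled arrays these medians become -0.07 for interferon genes, with none past 2-fold, and 0.34 for collagens and matrix. Fibroblast markers had a median of -0.89 over 11 genes, with S100a4 (-1.56), Col1a2 (-1.24) and Pdgfra (-1.23) past 2-fold. Immediate early genes had a median of 0.58 with 7 positive, among them Jun, Maff (1.57) and Fosl1 (1.38), and ribosome biogenesis and MYC targets 0.52 with 3 positive, Gnl3 (1.26), Nop2 (1.15) and Rrp12 (1.01). For p53 targets the median was 0.51, yet the members split: Aen (1.41) and Ccng1 (1.14) were positive while Sesn1 (-1.94) and Ddb2 (-1.03) were negative. In the reverse order the medians are 0.13 for fibroblast markers, -0.27 for immediate early genes, 0.72 for ribosome biogenesis and 0.01 for p53 targets. In the osmolyte and tonicity list 8 of 24 genes were at least 2-fold negative and 2 positive, the creatine transporter gene Slc6a8 (1.21) and the choline kinase gene Chka. Its median of -0.14 lay within the range of random lists (percentile 20.81). This too rests on the order of the knockout-labelled arrays: in the reverse order the median is -0.41, with 5 genes at least 2-fold negative and 1 positive.

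**Figure D2:**
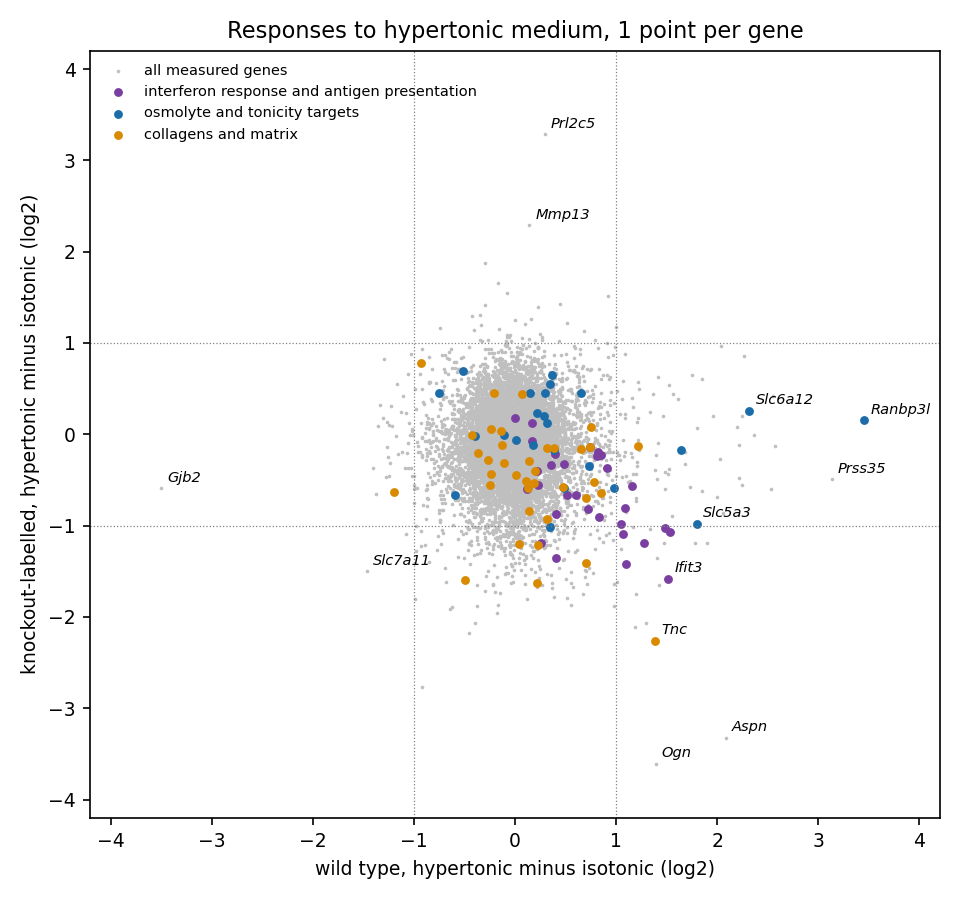
Hypertonic minus isotonic log2 difference of each of 10542 genes in wild-type cells (horizontal) and knockout-labelled cells (vertical), with dotted lines at 2-fold and the measured members of 3 lists in colour. Interferon genes lie to the lower right, with medians of 0.73 and -0.63, and the largest tonicity genes, Ranbp3l and Slc6a12, lie far right at vertical values of 0.15 and 0.26. Those vertical values come from signals below the dim limit on both knockout-labelled arrays.

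**Figure D3:**
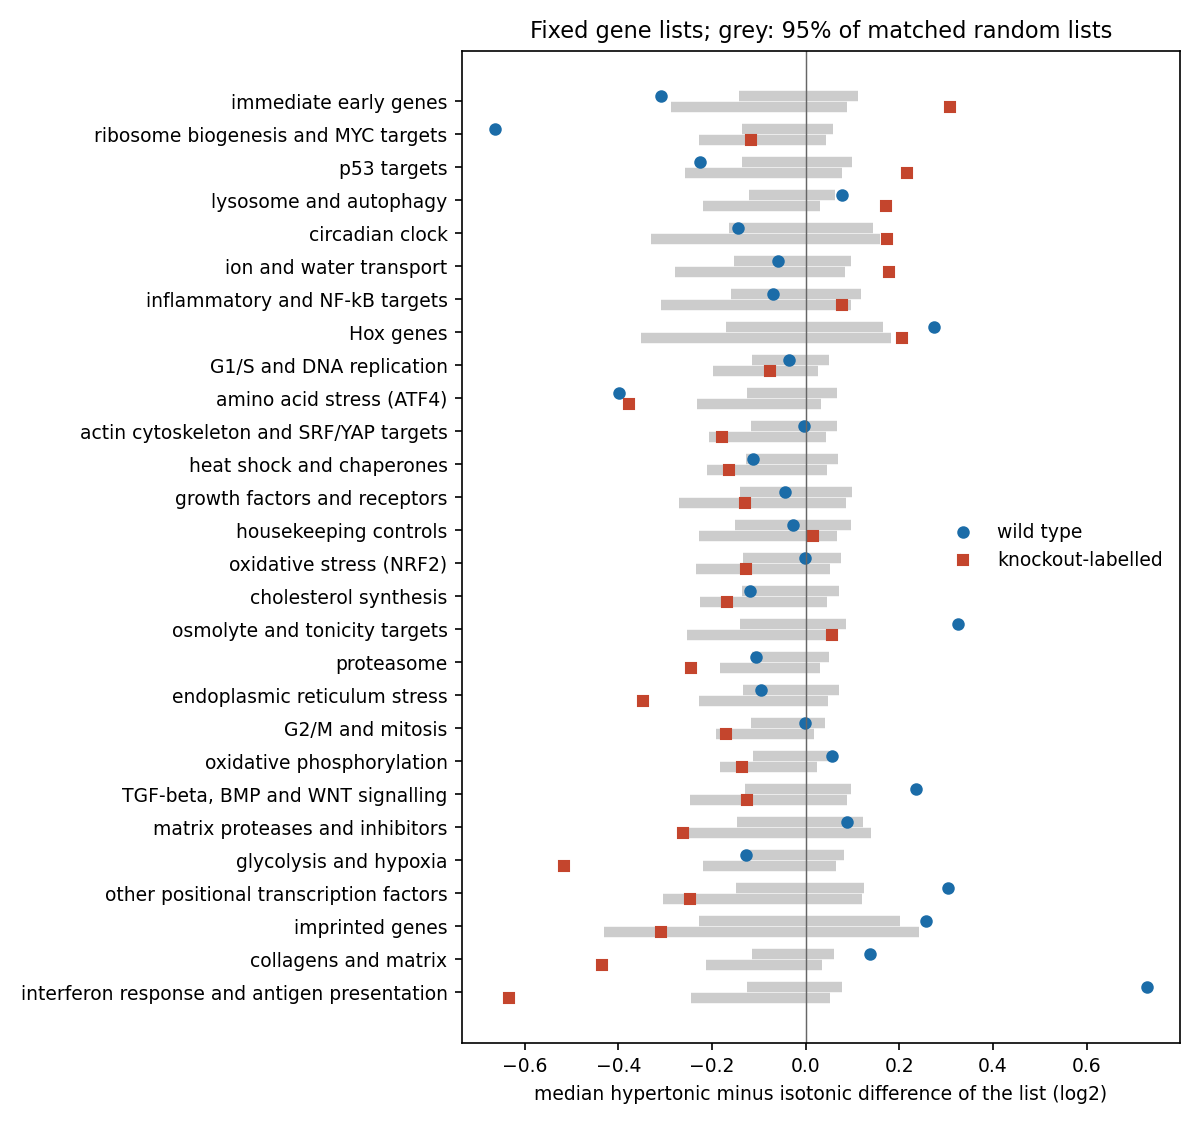
Median hypertonic minus isotonic log2 difference of each fixed pathway list with at least 3 measured genes in wild-type cells (circles) and knockout-labelled cells (squares), with grey bars spanning the middle 95% of matched random lists. Immediate early genes had medians of -0.31 and 0.31, and the amino acid stress list -0.40 and -0.38.

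The third comparison asked how the knockout-labelled cells differed from wild-type cells in isotonic medium. Among the genes with the largest positive differences were the transcription factor genes Tfap2b (3.74), Hoxd10 (3.32), Sox2 (2.87), Hoxd11 (2.59), Sim2 (2.47) and Tfap2a (2.41). Ifi202b, an interferon-inducible gene, had the largest (5.44), from a wild-type signal of 3.19. The wild-type signals of Ifi202b and of the transcription factor genes other than Hoxd11 lay below the dim limit. Xist, the RNA that silences an X chromosome in female cells, was lower (-5.25), reading 8.99 in wild-type cells and 3.75, below the dim limit, in knockout-labelled cells. Also lower were Cd34 (-4.28), a surface marker of progenitor cells, Foxf2 (-2.82), the retinaldehyde dehydrogenase gene Aldh1a1 (-2.58), Meox2 (-2.35) and S100a4 (-2.24), of which Foxf2, Aldh1a1 and Meox2 read below the dim limit in knockout-labelled cells. Counting all measured genes, 10191, there were 162 at least 2-fold higher and 130 at least 2-fold lower, with the smaller signal below the dim limit for 62 and 57 of them. With the other knockout-labelled array in its place, 218 are higher and 485 lower.

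Of the 14 measured Hox genes, Hoxd10, Hoxd11, Hoxa13 (1.51) and Hoxd13 (1.36) were at least 2-fold higher and Hoxb9 (-1.72) was lower; the list's median of 0.24 became -0.10 when dim genes were included and 1.36 with a dim limit at the 75th percentile. Other positional transcription factors (median 0.13 over 21 genes, 2 higher and 2 lower) and neural and Schwann markers (-0.15 over 6 genes, 2 higher and 2 lower) lay within the range of random lists. Interferon genes were higher in the knockout-labelled cells already in isotonic medium, with a median of 0.80 (percentile 100) and 11 of 30 past 2-fold, all upward. Oas2 (2.03), Mx1 (1.56), Iigp1 (1.56) and Irf7 (1.34) had the largest differences. This rests on the order of the knockout-labelled arrays: in the reverse order the median is 0.28, with 1 of 30 past 2-fold. Collagens and matrix genes had a median of -0.44 (percentile 0.0) with 8 of 37 at least 2-fold lower, among them Vcan (-1.73), Lama4 (-1.51), Fbln2 (-1.49) and Mfap5 (-1.47). In the actin cytoskeleton and SRF/YAP list, with a median of -0.25 (percentile 0.0), 5 of 28 genes were at least 2-fold lower, among them Tagln (-2.08), Ankrd1 (-2.02) and Acta2, smooth muscle actin (-1.50), and 7 were above 0. The osmolyte and tonicity list had a median of -0.20 (percentile 0.01), with the amino acid transporter gene Slc38a4 (-2.25) and S100a4 at least 2-fold lower. In the reverse order its median is -0.10, with 3 genes at least 2-fold higher and 6 lower. Collagens and matrix then have a median of -0.89, with 15 of 37 genes at least 2-fold lower. The actin list has -0.39 in that order and the Hox list 0.50.

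The labels name 1 cell population per genotype, so genotype and cell isolate cannot be told apart here. Probe differences had an SD of 0.18 per probe over 615 genes, and in simulated data 96.0% of 3-fold changes and 0.06% of unchanged genes passed 2-fold.

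The fourth comparison set knockout-labelled against wild-type cells in hypertonic medium. Some tonicity genes read lower in the knockout-labelled cells: Cryab (-3.86), S100a4 (-3.81, next to -2.24 in isotonic medium), Slc5a3 (-3.59), Ranbp3l (-3.39), Aqp1 (-2.74) and Slc6a12 (-2.24). In the reverse order of the knockout-labelled arrays these 6 differences lie between -3.54 and -2.50. The matrix genes Aspn (-6.83), Tnc (-4.92) and Ogn (-4.41) and the growth factor binding protein genes Igfbp5 (-4.81) and Igfbp7 (-4.57) were lower too. The knockout-labelled hypertonic signals of Aspn (4.16), Tnc (5.09), Ogn (3.90), Igfbp5 (3.85), Ranbp3l (3.38) and Slc6a12 (4.14) lay below the dim limit, so the sizes and order of their differences are poorly determined. Higher genes included Gpnmb, encoding a transmembrane glycoprotein (3.90), Tfap2b (3.96), Hoxd10 (3.33), Sox2 (3.24), Mmp13 (2.70) and Pdgfb (2.57); all of these but Gpnmb read below the dim limit in wild-type cells. Counts were 267 at least 2-fold higher and 667 at least 2-fold lower among 10374 measured genes, with the smaller signal below the dim limit for 88 and 215 of them. With the other knockout-labelled array in its place, 190 are higher and 261 lower.

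Of the osmolyte and tonicity list, 10 of 24 genes were at least 2-fold lower and 2 higher, Chka (1.67) and the aldo-keto reductase gene Akr1b10, with a median of -0.49 (percentile 0.02, interval -2.18 to 0.27) and 9 above 0. Collagens and matrix genes had the lowest median of the lists with over 20 genes, -1.18, with 21 of 37 at least 2-fold lower and Lamb1 (1.62) higher. Lama4 (-3.35), Vcan (-2.98), Mfap5 (-2.92) and Fmod (-2.81) were also lower, all to signals below the dim limit. Fibroblast markers had a median of -0.69 with 5 of 11 lower, and imprinted genes -1.29, or -0.49 with dim genes included, with 6 of 9 lower, among them Mest (-2.62) and Peg3 (-2.59), again to signals below the dim limit. The p53 target list had a median of 0.57 (percentile 100). Mdm2 (1.67), Eda2r (1.60), Trp53inp1 (1.51) and Ccng1 (1.45) were among 7 of 26 genes higher, and Sesn1 (-1.84) was lower. Interferon genes, higher in knockout-labelled cells in isotonic medium, had a median of -0.42 in hypertonic medium (percentile 0.01), with 6 of 30 at least 2-fold lower and Ifit3 lowest (-2.34). Their median is 0.18 in the reverse order, and that of collagens and matrix is -0.78. The osmolyte and tonicity list then has a median of -0.57 and fibroblast markers -0.22. Imprinted genes have -0.59 in that order, with 3 of 9 at least 2-fold lower. For p53 targets it is 0.34, with 1 gene at least 2-fold higher and 1 lower.

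Genotype differences in the separate media shared no array and correlated across 10542 genes with Pearson's r of 0.50 and Spearman's rho of 0.36. Of the 162 genes higher in knockout-labelled cells in isotonic medium, 65 were at least 2-fold higher in hypertonic medium, against 4.32 for independent lists, and 9 were lower. Those 9 compare with 10.78 for independent lists. Of the 130 lower genes, 95 were lower in hypertonic medium, against 8.65, and none was higher, against 3.46. Probe differences had an SD of 0.23 per probe over 614 genes. In simulated data for this comparison 90% of 3-fold changes passed 2-fold, and 3.62% of unchanged genes did, with noise set in the same way.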

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

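The tests for swapped labels, with the values in reverse order, and for male cells, the share of higher genes set against 50%, and the counts among the shortest and longest genes were chosen after the results were seen. Differences between the responses of the genotypes were not tested, since each group has 1 array; the results below stand out because the genotypes lay on opposite sides of 0.

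Interferon genes were higher in hypertonic medium in wild-type cells (median 0.73) and lower in knockout-labelled cells (-0.63), a difference of responses with a median of -1.27. Scaling of the arrays as a whole is argued against by its small size. The normalizations moved the median of all genes from -0.0247 to at most 0.0108 in the wild-type response. In the knockout-labelled response they moved it from -0.0874 to at most 0.0127. The list median kept its sign in 6 of 6 combinations of a genotype and a normalization, but shifts that small could hardly have changed it. Leukocytes mixed into the cells stay open: their marker list lay at percentile 12.4 in the knockout-labelled and 52.3 in the wild-type response, but 1 of 14 markers, Cd68, passed the dim limit, so those values mostly describe background. A swap of the knockout-labelled arrays cannot be told apart from a true reversal. The responses were uncorrelated across genes (r -0.0248), and a swap would only turn the sign of r, so that value decides nothing. The amino acid stress list (-0.40 and -0.38) and Slc7a11 (-1.46 and -1.50) were lower in both genotypes as labelled. On the other side, 20 genes reversed against 3.28 for independent lists, as did Slc5a3 (1.80 and -0.98), and interferon genes already stood higher by 0.80 in knockout-labelled isotonic cells; of the 8 pathway lists outside the random range in both responses, 4 had the same sign and 4 opposite signs, and under quantile normalization 2 and 4 of them stayed outside. If no array was swapped, the hypothesis that NFAT5 status changes how hypertonic medium acts on interferon genes stays open beside a difference between cell isolates, neither tested.

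In knockout-labelled cells, genes at least 2-fold lower in hypertonic medium outnumbered those higher, 317 to 39, and a swap of the knockout-labelled arrays, left open above, would turn this to 39 lower and 317 higher. Intensity-dependent scaling is argued against as the whole cause, since the ratio of lower to higher genes was 6.9 after cyclic loess. Quantile normalization cut the lean further, to 215 lower and 63 higher, so scaling as part of the cause stays open. Greater scatter met the criterion set for it beforehand, with a robust SD over probes of no gene 1.421 times that of the wild-type pair. Symmetric scatter alone would leave 50% of the genes higher, and after centring 22.07% were (exact 95% interval 17.5% to 27.21%, counting error only). Skewed scatter stays open: probes of no gene, whose kinds were not separated, leaned the same way, 311 lower to 54 higher. Those probes also leaned down in the wild-type response, 152 lower to 67 higher, where named genes leaned up, 42 lower to 102 higher. Probes of several genes gave 3 lower and 4 higher in knockout-labelled cells, with a robust SD of 0.2175 against 0.1498 in the wild-type pair. Loss of signal growing with gene length may add to the lean and stays open: the longest 25% of genes minus the shortest 25% gave a median difference of -0.083 (interval -0.109 to -0.058), with 90 lower and 7 higher among the longest and 55 lower and 16 higher among the shortest. Length here is the genomic span of a gene, not the length of its transcript. The interval comes from resampling the genes of 1 pair of arrays. A biological loss of transcripts under stress without NFAT5 was not separated from lower RNA quality in that pool.

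Xist read 8.99 and 9.31 in wild-type and 3.75 and 3.16 in knockout-labelled cells. Male cells on the knockout-labelled arrays are argued against, since the highest signal of a Y-linked gene there was 3.05, below the dim limit, although no array here gave a signal that would show these probes responding. Loss of a whole X chromosome or of its silenced copy is a candidate explanation: 8 genes known to escape X silencing had a median genotype difference of -0.34 in isotonic and -0.46 in hypertonic medium. That evidence is thin, since it rests on 8 genes, of which 5 and 6 were below 0. The 313 measured X-linked genes had a median of 0.09 in isotonic medium (percentile 99.98 among autosomal sets). In hypertonic medium it was -0.06, in the opposite direction (percentile 2.78). Genes already silent on the lost copy would not fall with it, so these medians of all X-linked genes do not decide the question. Loss of Xist alone was not tested.

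Other groups also lay on opposite sides of 0 in the genotypes. Immediate early genes had a median difference of responses of 0.58, p53 targets 0.51, and collagens and matrix genes -0.62, all resting on the order of the knockout-labelled arrays; in the reverse order they are -0.27, 0.01 and 0.34. At the level of genes, 20 were at least 2-fold higher in wild-type and at least 2-fold lower in knockout-labelled cells.

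Probes to which the annotation gives no gene, left out of all gene results, also held differences of at least 2-fold. What these probes target was not examined, and kinds of probe among them were not separated. In hypertonic medium 67 were higher in wild-type and 54 in knockout-labelled cells, next to 152 and 311 lower, and in isotonic medium 134 were higher and 114 lower in knockout-labelled than in wild-type cells. The same genotype difference in hypertonic medium had 98 higher and 210 lower.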

How the results depend on the processing

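All alternatives were set before the data were examined. Of the counts and correlations, 69 stayed within 1.5 times (counts) or 0.1 (correlations) of their value and 25 did not. Of 450 list medians, 413 stayed within 1.5 times and 37 did not, 11 of them with no limit on dim genes and 16 with the stricter limit. Of the differences of the highest and lowest named genes, 479 stayed within the SD between probes and 1 moved. Much of that was fixed in advance. All of these genes but Mpp6 had 1 probe set, so the mean of probe sets could not move them. Centring shifts each difference by less than that SD. The dim-limit alternatives were not applied to these genes. In the knockout-labelled response, the number of higher genes was 63 after quantile normalization and 66 after centring on the median, against 39; centring adds 1 amount to every difference, and for quantile normalization the cause was not tested. Cyclic loess and the mean of a gene's probes moved no count by 1.5 times. Without a limit on dim genes, 246 genes had a positive difference of responses against 149, and the genotype differences correlated with r of 0.3773 and rho of 0.1971; the cause is the added dim genes. With the dim limit at the 75th percentile fewer genes were counted, by construction. Higher and lower genes were then 49 and 20 in the wild-type response, 11 and 110 in the knockout-labelled response, 71 and 41 for genotype in isotonic medium, 138 and 319 in hypertonic medium, and 68 and 270 for the difference of responses. With a limit of 1.5-fold more genes were counted, by construction: 418 and 334, 440 and 1237, 501 and 394, 905 and 1562, and 818 and 1624 in the same order. The Hox list reversed in the isotonic genotype difference, to a median of -0.1032 without a limit on dim genes (1.3645 with the stricter limit), and the neural and Schwann list in the difference of responses, to -0.0699 with the stricter limit; both add or drop genes. Leave-one-out could not be run with 1 array per group, and the alternatives for linear values did not apply to log2 values. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers. A fit of genotype plus medium, which takes the difference of responses as error with 1 degree of freedom, was not used here. Signals below the dim limit bound what can be said of genes such as Ranbp3l (3.31 in isotonic wild-type cells).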

Other observations

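Other gene groups differed in ways not described above. Genes of TGF-beta, BMP and WNT signalling were, as a list, lower in knockout-labelled than in wild-type cells in hypertonic medium (median -0.43, or -0.22 with dim genes included), where Ltbp2 (-2.58), Grem1 (-2.44), Wnt5a (-2.22) and Fzd1 (-1.78) were lowest and 6 of 29 passed 2-fold, all downward. The actin cytoskeleton and SRF/YAP list had a median of -0.37 there, with Myl9 (-2.52), Acta2 (-2.50) and Tagln (-2.30) lowest. Ribosome biogenesis and MYC targets were higher there (0.37, percentile 99.99), with Utp20 (1.11) and Gnl3 (1.09) past 2-fold. The lysosome and autophagy list had a median of 0.20 in the same comparison, with Gla, the alpha-galactosidase gene, higher (1.27) and Naglu lower (-1.14). These medians rest on the order of the knockout-labelled arrays. In the reverse order the TGF-beta, BMP and WNT list has a median of -0.09, with 5 genes at least 2-fold lower and 1 higher. The actin list then has -0.12, ribosome biogenesis 0.48, and lysosome and autophagy 0.02.

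Among matrix proteases and their inhibitors, members went both ways in knockout-labelled cells in hypertonic medium. Mmp13 (2.29) and Mmp10 (1.66) were higher, while Adamts5 (-1.89), the inhibitor gene Timp3 (-1.51), Serpinf1 (-1.25) and Adamts1 (-1.06) were lower. The NAD(P)H quinone dehydrogenase gene Nqo1 differed by 0.83 in wild-type and -1.14 in knockout-labelled cells, in an oxidative stress list with medians of 0.00 and -0.13.

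Markers of other cell types were mostly dim. Apart from Cd68, Flt1 was the 1 endothelial marker above the dim limit, Pparg was the 1 adipocyte marker, Col2a1 and Sox9 were the cartilage and bone markers, and no erythroid marker was. Skeletal muscle and epithelial markers had no member past 2-fold in any comparison. Among neural and Schwann markers, Sox2 and Stmn2 were higher in knockout-labelled isotonic cells (2.87 and 3.34), and Tubb3 (-2.09) and Nes (-1.34) were lower.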
